A study of Homo sapiens with 8 samples.

How the data were processed

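Total RNA of HMLE cells was labelled with biotin and hybridised to single-colour Affymetrix arrays, per the labels' protocols. Arrays were grouped by their labels into CD24hi, MSP1, MSP2 and MSP3, with 2 arrays each, named a and b. Nothing in the labels says that arrays a and b came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The cells are an established line.

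The values used were the deposited probe set signals, a linear intensity for each probe set and array. Affymetrix Expression Console and limma are named in the submitters' processing notes, without versions. The algorithm, its parameters and the genome build are not given in the sources used here. The deposited intensity values were above 0 on every array and had the same 2% trimmed mean of 150, with quartiles that differed between arrays, so they had been scaled but not quantile normalized. A second file holds the authors' own comparisons of each MSP group with CD24hi, as a log2 fold change, an average log2 level and a p-value, per the file headers. Whether the deposited p-value is adjusted for multiple tests is not stated in the header; between 53.7% and 59.2% of the values were tied with another. The slope of the deposited on the present fold changes was 0.53 in each comparison.

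The authors' table was the only source of gene names. It opened with 2256 probe sets that had a p-value at or under 0.05 in all 3 comparisons, and went on in array order up to position 14644 of the array, where it ended. It listed 16382 probe sets, of which 14026 had 1 symbol, 2331 none, 2 several and 23 a symbol turned into a date. Of the symbols, 6490 were current in the RefSeq gene table of assembly GRCh38.p14, 1299 were updated through a synonym and 1163 were kept as listed. This gave 8926 genes, 8121 with a probe set in the completely named part and 805 named only through the authors' calls. Each gene was represented by the named probe set with the highest mean over the 8 arrays, and 1078 of these 8926 probe sets lay outside the completely named part. Of 3332 genes with more than 1 named probe set, 2 had probe sets called in both directions. The remaining probe sets of the array had no gene name here and entered only counts over all 54613 probe sets, after 62 control probe sets were left out.

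Signals were log2 transformed with no offset and fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 8 arrays (4 residual degrees of freedom) and eBayes moderation (1.94 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Contrasts set each MSP group, and the mean of the 3 with equal weight, against CD24hi, and each MSP group against each other. A change is given as log2 change ± SE of the fit, two-sided, with n = 2 arrays per group, and a level as the geometric mean signal of a group. Because the residual SD rose from 0.31 log2 units above 512 signal units to 0.53 between 16 and 32 and 1.14 under 8, levels under 32 were treated as dim. Where the lower side was dim, the fold is the brighter level over 32 and is written "at least N-fold", and where both sides were dim no fold is given; this limit was set after the values were seen.

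The 31 gene lists, the contrasts, the main alternatives and the rule for named genes were written before the data were examined. The rule took CD24, CD44, CDH1, CDH2, VIM, FN1, ZEB1 and ESRP1 always; the 12 widest rises and 12 widest falls of the mean contrast among genes called in all 3 single contrasts; the 5 widest rises and 5 widest falls of each single contrast whose arrays did not overlap; and the 2 widest called rises and falls of each list, or its brightest member where none was called. It passed over genes with no symbol, LOC and open-reading-frame names, and some genes used to infer sex. It gave 87 genes, 82 of them called. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. No list was called with an estimated correlation. For the list of epithelial transcription and splicing factors that estimate was 0.01, equal to the preset, and for the luminal list 0.02. The loss of their calls therefore cannot be put down to a higher correlation alone. The design had assumed a gene name for every probe set of the array, so counts over all probe sets and over the completely named part were added.

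Comparisons with CD24hi share its arrays, so 20 data sets of unchanged MSP groups against the same arrays were simulated. The fit was tested on simulated data for the 8926 genes with known changes. For the mean of the MSP groups against CD24hi it called 2% of genes changed 2-fold and 38% of those changed 4-fold. It called 68% of those changed 8-fold and 78% of those changed 16-fold, and 3.92% of its calls were false. These simulated arrays had the same spread in every group for a given gene. In the data, CD24hi arrays a and b stood further apart. Over bright probe sets the SD of their difference was 0.86, against 0.38 to 0.52 in the MSP groups. The simulated shares therefore do not show how many calls against CD24hi are false or missed in these data. Nor do they show it between the MSP groups, whose simulated spread also drew on the CD24hi arrays. Alternatives were quantile normalization, median centring, the mean of a gene's probe sets, the probe set with the largest interquartile range, a filter on dim genes, eBayes with trend and robust, a fit of only the groups compared, the replicate letter as a block, each array left out, stricter thresholds, and for the mean contrast a random block per subpopulation, subpopulation means, and each subpopulation left out. An offset of 16, a floor of 32, all probe sets, the completely named part and the MSP arrays alone were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.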

Results

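Gene expression was measured in HMLE cells, an immortalized line of human mammary epithelial cells, with 8 single-colour Affymetrix arrays. The arrays fell into 4 groups of 2, each with an array a and an array b. CD24hi held cells sorted for high surface CD24, an epithelial marker. MSP1, MSP2 and MSP3 were 3 mesenchymal subpopulations of the same line. Each array gave a signal for the same probe sets, 54613 of them without controls, and the 2% trimmed mean signal was 150 on every array. The median signal ran from 15.5 on CD24hi array b to 20.2 on CD24hi array a. Between 57.6% and 60.3% of probe sets lay under 32 signal units, where the spread between arrays was widest. With 2 arrays per group, the number of arrays limits the precision of every value. The comparisons asked how the mesenchymal subpopulations differed from the CD24-high epithelial cells, and how the 3 subpopulations differed from each other.

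The epithelial and mesenchymal arrays separated along the first principal component, which held 61.8% of the variance over 13551 bright probe sets. CD24, the marker used for the sort, had a signal of 4934 in CD24hi against 22.3 in MSP1, 106 in MSP2 and 92.5 in MSP3 on the probe set used here, which set CD24hi apart from the MSP arrays as labelled and bears on no difference among these. Over the completely named part of the array, where another CD24 probe set stood for the gene, its log2 change was 0.06. The CD24hi arrays stood further apart than the pairs of any MSP group: 23.5% of bright probe sets differed over 2-fold between CD24hi a and b, against 1.31% in MSP1, 4.75% in MSP2 and 5.65% in MSP3. The Bacillus control transcripts read 720 on CD24hi a and 70.3 on CD24hi b, against 188 to 285 on the MSP arrays. The 3′ to 5′ ratio of ACTB was 1.47 on CD24hi a and lower on each other array, down to 1.10 on CD24hi b.

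**Figure D1:**
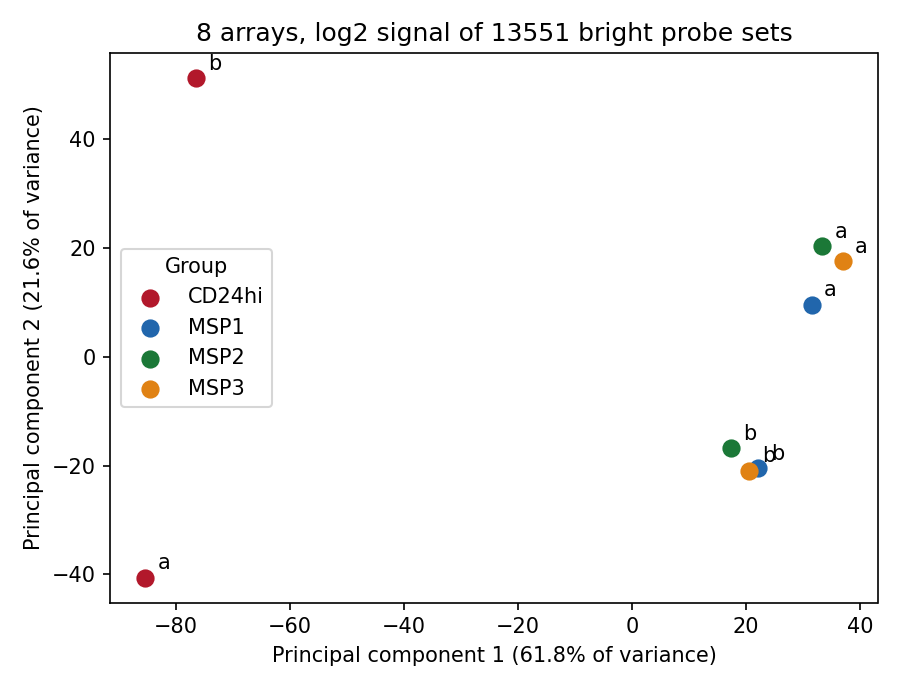
Position of the 8 arrays on the first 2 principal components of log2 signal, with each point an array, coloured by group and lettered by replicate. The CD24hi arrays lie at -85.3 and -76.5 on component 1 and the MSP arrays between 17.3 and 37.0, while component 2 parts CD24hi a from b (-40.6 and 51.2).

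Genes of epithelial adhesion fell in the mesenchymal subpopulations, in the comparison of the mean of the 3 MSP groups with CD24hi. CDH1, which encodes E-cadherin, had a signal of 4339 in CD24hi and 7.94 in the MSP mean, at least 136-fold lower (log2 change -9.09 ± 0.86 SE, n = 2 arrays per group, adjusted p = 0.0019). CDH3, the P-cadherin gene, was at least 72.6-fold lower (log2 change -8.57 ± 0.74), EPCAM, an epithelial adhesion molecule, at least 117-fold lower (-8.05 ± 0.47), and RAB25, a GTPase of epithelial vesicle traffic, at least 18.3-fold lower (-7.95 ± 0.73). Of the 28 measured members of the epithelial adhesion and junction list, 27 fell and 0 rose, and 27 fell when adjusted over the list alone. The list shifted down with camera (adjusted p = 1.24e-22), and had an adjusted p = 0.127 with an estimated correlation. Of its members, 11 were named only because the authors had called them, and among the 17 others 16 fell. Here and in the lists below, such others are genes with a probe set in the completely named part. Their call is that of the brightest probe set, which may lie outside that part, so these counts are not free of the authors' choice.

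Transcription factors and splicing regulators of epithelial cells fell as well. ESRP1, an epithelial splicing regulator, went from 1192 to 2.54, at least 37.3-fold lower (log2 change -8.87 ± 0.52, adjusted p = 7.58e-04). TP63, a master regulator of basal epithelium, was at least 41.0-fold lower (-7.63 ± 0.92, adjusted p = 0.00414), though another TP63 probe set, from the completely named part of the array, changed by -1.41 and was not called. In this list 12 of 15 measured members fell, or 13 when adjusted over the list alone, with a camera adjusted p = 1.70e-09 and an adjusted p = 0.0884 with an estimated correlation. The authors' calls were the only source of a name for 9 of the 15, and 4 of the 6 others fell. TP63 is among those 4 only through a probe set outside the completely named part.

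Basal keratins and hemidesmosome genes fell in 13 of 15 measured cases, a count that was the same when adjusted over the list alone. COL17A1, a hemidesmosome collagen, was at least 36.2-fold lower (log2 change -9.18 ± 0.39), and KRT6B went from 6653 to 40.0, 166-fold lower (-7.38 ± 0.33), each with adjusted p = 7.25e-04. ITGA6, a laminin receptor subunit, went from 5301 to 709 (-2.90 ± 0.69, adjusted p = 0.0387), a call lost in 7 of the 8 fits that left out an array, all but MSP2 b, where the change ran from -3.42 to -2.39. Of its members 4 were named only through the authors' calls, and 9 of the 11 others fell. The basal list had a camera adjusted p = 7.29e-10 and an adjusted p = 0.129 with an estimated correlation. The luminal keratins KRT8 and KRT18 fell 31.2-fold (-4.96 ± 0.34) and 23.0-fold (-4.53 ± 0.25). The luminal list had 4 of 11 members lower, 6 when adjusted over the list alone, and 3 of the 9 not named through the authors' calls alone, with a camera adjusted p = 5.47e-04 and an adjusted p = 0.129 with an estimated correlation.

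Genes of epidermal differentiation fell in 9 of 10 measured cases, and in 10 when adjusted over the list alone. SPRR1B, a cornified envelope protein, was at least 46.5-fold lower (log2 change -8.31 ± 0.87, adjusted p = 0.00261), and CRCT1 fell from 26.8 to 0.594 signal units, both within the dim range, so no fold is given. This list had a camera adjusted p = 2.50e-08 and an adjusted p = 0.129 with an estimated correlation, and 6 of its 10 members were named only through the authors' calls, with 3 of the 4 others lower. Outside these lists, falls common to all 3 subpopulations included GJB6, a gap junction protein, at least 18.4-fold lower (-10.51 ± 0.89), PNLIPRP3, at least 23.2-fold lower (-7.84 ± 0.61), and SERPINB2, a plasminogen activator inhibitor, at least 26.1-fold lower (-8.32 ± 1.35). The SERPINB2 call was lost without CD24hi a, at a log2 change of -6.47.

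**Figure D2:**
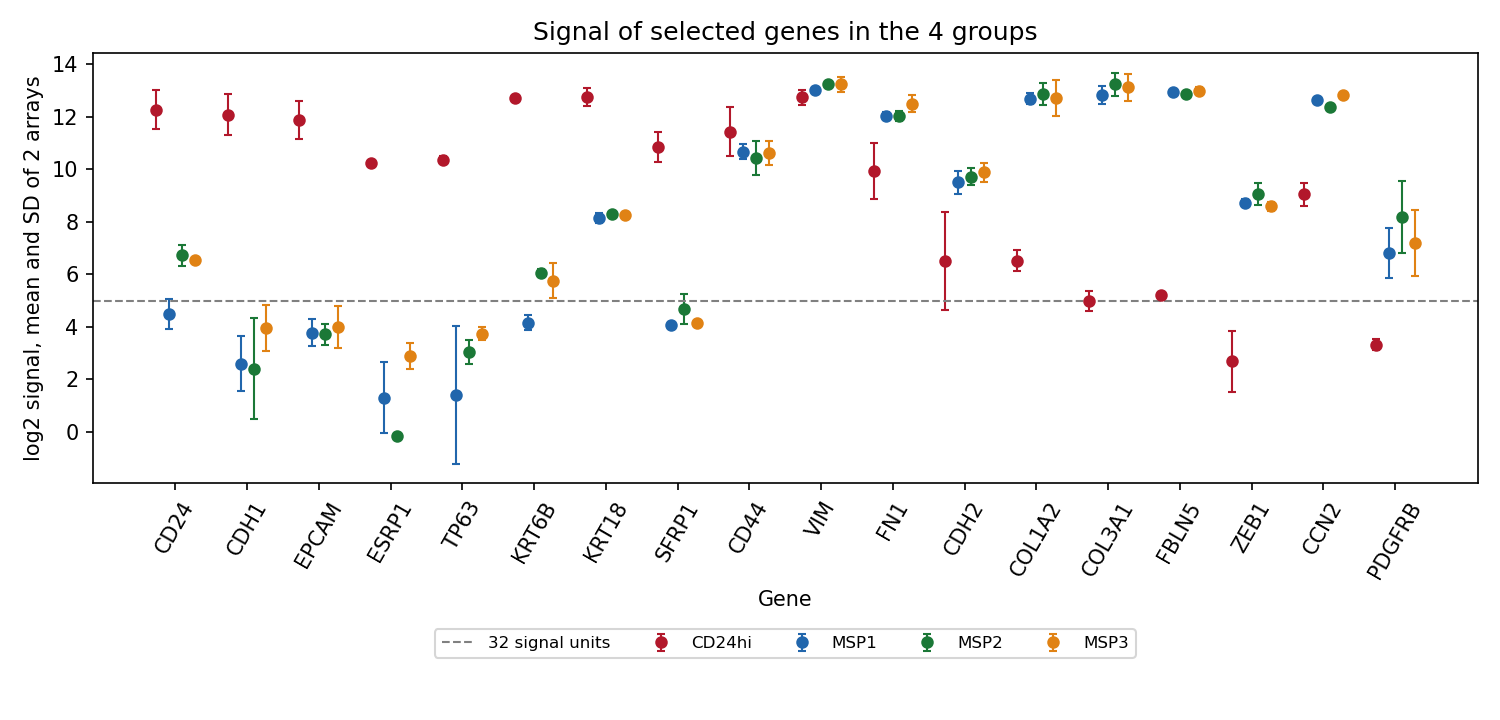
Log2 signal of 18 genes in the 4 groups, with points at the mean of 2 arrays, bars of ± 1 SD, and a dashed line at 32 signal units. CDH1, EPCAM and ESRP1 lie above the line in CD24hi and below it in every MSP group, COL3A1 lies at 31.5 signal units in CD24hi and at 7224 or more in every MSP group, and VIM and CD44 lie above the line in all 4 groups.

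Collagens and other matrix genes rose in the mesenchymal subpopulations. COL3A1 went from 31.5 to 8507, at least 266-fold higher (log2 change 8.08 ± 0.35, n = 2 arrays per group, adjusted p = 7.25e-04). FBLN5, an elastic fibre protein, rose 209-fold from 37.0 to 7738 (7.71 ± 0.21, adjusted p = 3.18e-04), and COL1A2 rose 75.9-fold (6.25 ± 0.37). COL6A2 was at least 9.67-fold higher (7.18 ± 0.44), and PCOLCE, which aids procollagen processing, at least 51.9-fold higher (7.29 ± 0.61). Of 22 measured matrix genes, 16 rose and 1 fell, and 17 rose and 1 fell when adjusted over the list alone. Among the 17 not named through the authors' calls alone, 12 rose and 0 fell. The gene that fell was MFAP5, a microfibril protein, at least 20.8-fold lower (-5.36 ± 0.34). The list had a camera adjusted p = 3.37e-10 and an adjusted p = 0.260 with an estimated correlation, and its median a minus b difference between the CD24hi arrays was 0.96 on the log2 scale.

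Stromal fibroblast markers rose in 8 of 14 measured cases and fell in 2, the same counts as when adjusted over the list alone. PDGFRA and PDGFRB, the platelet-derived growth factor receptors, were at least 3.59-fold and 5.25-fold higher (log2 changes 4.91 ± 0.63 and 4.07 ± 0.73). With the mean of its probe sets PDGFRA changed by 1.80 and was not called. The PDGFRB call was lost without either CD24hi array, at log2 changes of 3.93 and 4.21. PDPN, a mucin-type membrane protein, was lower (-4.64 ± 1.18, adjusted p = 0.0496), a call lost in 6 of 8 fits that left out an array, all but those without MSP1 a or MSP1 b (range -5.37 to -3.90). Among the 12 members not named through the authors' calls alone, 7 rose and 1 fell. The fibroblast list had a camera adjusted p = 0.00149 and an adjusted p = 0.311 with an estimated correlation.

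Classical mesenchymal markers changed less uniformly. CDH2, the N-cadherin gene, rose 9.16-fold from 91.0 to 833 (log2 change 3.20 ± 0.69, adjusted p = 0.0285), but the call was lost in 7 of 8 fits that left out an array, all but CD24hi a, and the change was 1.88 without CD24hi b. FN1, fibronectin, rose 4.72-fold (2.24 ± 0.44, adjusted p = 0.0203), a call lost without MSP1 a, MSP1 b, MSP2 a or MSP3 a (2.16 to 2.28). FN1 rose 2.79-fold without CD24hi b and 7.98-fold without CD24hi a. MYL9, a myosin light chain, was at least 11.7-fold higher (3.64 ± 0.65), and its call was lost without either CD24hi array (3.31 and 3.97). VIM, vimentin, read 6848 in CD24hi and 9204 in the MSP mean (0.43 ± 0.25, adjusted p = 0.373), and CD44 read 2760 and 1520 (-0.86 ± 0.47, adjusted p = 0.331). The list had 5 of 18 members higher and 0 lower, 6 and 0 when adjusted over the list alone, with a camera adjusted p = 0.0102 and an adjusted p = 0.311 with an estimated correlation. Without CD24hi b its adjusted p was 0.055.

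Transcription factors of the epithelial-mesenchymal transition rose in 6 of 13 measured cases and fell in 1, or 7 and 1 when adjusted over the list alone. ZEB1, a repressor of CDH1, went from 6.44 to 443, at least 13.8-fold higher (log2 change 6.10 ± 0.47, adjusted p = 0.00123). FOXQ1, a forkhead factor, was at least 2.48-fold lower (-2.86 ± 0.37). Both were named only through the authors' calls, as were 5 of the 13, and among the 8 others 2 rose and 0 fell. The list had a camera adjusted p = 0.0178 and an adjusted p = 0.347 with an estimated correlation. Its adjusted p was 0.0911 without CD24hi b, and 0.629 over the completely named part of the array.

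Among the other genes that rose in all 3 subpopulations, RTN1, a reticulon of the endoplasmic reticulum, went from 0.72 to 334, at least 10.4-fold higher (log2 change 8.86 ± 0.42). SDC2, a heparan sulfate proteoglycan, was at least 30.4-fold higher (8.34 ± 1.29), PTGFR, the prostaglandin F receptor, at least 19.9-fold higher (8.30 ± 0.72), and ITGBL1 at least 60.4-fold higher (7.67 ± 0.44). ACKR1, a decoy chemokine receptor, was at least 23.5-fold higher (7.10 ± 0.85), PDGFRL at least 12.9-fold higher (7.41 ± 0.44), and CNRIP1 at least 7.87-fold higher (7.23 ± 0.69).

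Over all genes, 1428 of 8926 were called between the MSP mean and CD24hi, 663 higher and 765 lower, of which 498 and 596 changed at least 2-fold with dim levels raised to 32 (638 and 755 as fitted), while 174 were dim on both sides. The balance turned to 798 higher and 699 lower among genes above the median level, and to 580 and 462 without CD24hi a. Gene names came from a table that listed probe sets called by the authors first, so 1078 of the 8926 probe sets used were named only because they had been called there, and these gave 901 of the 1428 calls. The other 7848 gave 527 calls, at a Benjamini-Hochberg cutoff set over all 8926, which the many calls among the 1078 loosened. Over all 54613 probe sets, named or not, 1731 were called, 861 higher and 870 lower, and 15 of the 82 called genes named in the text did not pass that wider adjustment. A floor of 32, chosen after the data were seen, ended the calls of 14 named genes: AXIN2, BMP2, CDH2, CRCT1, FOXQ1, IFI44L, ITGA6, KDR, LTBP2, NOG, OAS1, PDGFRB, SERPINB2 and WNT5B. Over the completely named part alone, also chosen after the data were seen, 56 of the 87 named genes had a probe set and 31 could not be tested. Of the 56, 10 lost their call (CDH2, INHBA, ITGA6, KDR, KLK8, LTBP2, RHOB, ROR1, TP63 and TYMS), and CD24 and HERC6 changed sign. Leaving out a CD24hi array moved the fitted fold by over 1.5 times in 26 of the 87, and for genes dim in CD24hi these shifts lie within the dim range. Without CD24hi b and without CD24hi a the log2 changes were 5.72 and 10.95 for SDC2, 5.41 and 8.79 for ACKR1, 5.98 and 8.48 for CNRIP1, 6.47 and 7.88 for COL6A2, 6.93 and 8.42 for ITGBL1, 8.42 and 6.16 for PCOLCE, 3.77 and 6.06 for PDGFRA, 9.35 and 7.26 for PTGFR and 6.92 and 5.28 for ZEB1. They were -11.39 and -9.63 for GJB6, -11.66 and -8.64 for KLK10, -8.46 and -7.22 for PNLIPRP3, -6.13 and -4.87 for CRCT1 and -1.51 and -0.21 for CD44.

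Wnt pathway genes went both ways. SFRP1, a secreted Wnt antagonist, went from 1844 to 19.7, at least 57.6-fold lower (log2 change -6.55 ± 0.34, adjusted p = 7.25e-04). It was the only member of the 7 measured secreted Wnt antagonists that passed the test, over all genes and when adjusted over the list alone. AXIN2, a feedback target of beta-catenin, was at least 2.66-fold higher (3.22 ± 0.37), while RNF43, another feedback target, was at least 2.77-fold lower (-5.30 ± 0.69) and MYC fell 2.92-fold (-1.55 ± 0.24). Among 7 beta-catenin targets 1 rose and 2 fell, or 1 and 3 when adjusted over the list alone. WNT5B rose 4.78-fold (2.26 ± 0.48), with its call lost in 7 of 8 fits that left out an array, all but CD24hi a, and a change of 1.38 without CD24hi b. WNT7A was at least 3.07-fold lower (-3.82 ± 0.69), a call lost without either CD24hi array (-3.92 and -3.71). Of 4 Wnt ligands 1 rose and 1 fell, or 1 and 2 when adjusted over the list alone. The receptor ROR1 rose 6.06-fold (2.60 ± 0.49) and FZD3 was at least 7.56-fold lower (-3.45 ± 0.30), leaving 1 of 6 receptors higher and 1 lower, also when adjusted over the list alone. ROR1 was not called with the mean of its probe sets (1.84), and its rise was 3.35-fold without CD24hi b and 10.97-fold without CD24hi a. None of the 4 Wnt lists passed the camera test, with adjusted p of 0.593 for ligands, 0.910 for antagonists, 0.927 for receptors and 0.450 for targets. With fry, another list test, the adjusted p were 0.00934 for ligands, 0.0264 for antagonists, 0.341 for receptors and 0.0141 for targets.

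TGF-beta and BMP pathway genes also split by member. LTBP1, which binds latent TGF-beta, rose 32.1-fold (log2 change 5.01 ± 0.48, or 21.2-fold without CD24hi b and 48.6-fold without CD24hi a), TGFBR3, a TGF-beta co-receptor, was at least 8.03-fold higher (3.64 ± 0.40), and INHBA, an activin subunit, fell 25.2-fold (-4.65 ± 0.42), a call lost over the completely named part of the array (-4.32). Of 9 ligands and receptors 3 rose and 1 fell, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.771). CCN2, a matricellular target of TGF-beta, rose 11.7-fold from 530 to 6219 (3.55 ± 0.26), LTBP2 rose 4.48-fold (2.16 ± 0.53), and PTHLH was at least 17.8-fold lower over all arrays (-4.15 ± 0.62, or -3.04 without CD24hi a and -5.27 without CD24hi b). The LTBP2 call was lost in 7 of 8 fits that left out an array, all but CD24hi a, and the rise was 2.37-fold without CD24hi b and 8.45-fold without CD24hi a. Of 13 TGF-beta targets 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.197). GREM1, a BMP antagonist, rose 49.4-fold (5.63 ± 0.84, or 4.31 without CD24hi b and 6.94 without CD24hi a) and FSTL1 2.70-fold (1.43 ± 0.32), while the antagonists FST and NOG were 44.7-fold and at least 3.39-fold lower (-5.48 ± 0.58 and -3.96 ± 0.87). The FST fall was 20.96-fold without CD24hi a and 95.5-fold without CD24hi b. The FSTL1 call was lost in 6 of 8 such fits, all but those without CD24hi a or MSP3 b (1.09 to 1.77), and the NOG call in 6, all but those without MSP3 a or MSP3 b (-4.82 to -3.10). Of 7 antagonists 2 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.611). Of 5 BMP ligands and targets ID2 was at least 3.17-fold higher (3.17 ± 0.33) and BMP2 at least 2.86-fold lower (-3.08 ± 0.70), and the same counts held when adjusted over the list alone (camera adjusted p = 0.980). The BMP2 call was lost in 6 of 8 fits, all but those without MSP1 b or MSP3 b (-3.68 to -2.48).

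Growth factor receptors, stem cell markers and secreted factors moved in both directions. FGFR3 and FGFR2, fibroblast growth factor receptors, were at least 36.6-fold and 8.02-fold lower (log2 changes -5.32 ± 0.51 and -5.29 ± 0.69), and 5 of 18 receptors rose and 5 fell, or 5 and 6 when adjusted over the list alone (camera adjusted p = 0.593). Among 7 stem cell and CD44-high markers, ALDH1A3, a retinaldehyde dehydrogenase, was at least 24.6-fold lower (-5.41 ± 0.38) and GNG11 at least 18.3-fold higher (4.43 ± 0.40). That list had 1 member higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 0.469). NRG1, an EGF family ligand, fell 13.1-fold (-3.71 ± 0.34) as the only one of 5 ligands called, against 3 lower when adjusted over the list alone (camera adjusted p = 0.0864). IL1A and IL1B, the interleukin-1 genes, were at least 27.5-fold and 13.9-fold lower (-8.49 ± 0.47 and -4.63 ± 0.57), and TSLP, an epithelial-type cytokine, was at least 13.9-fold higher (4.31 ± 0.33). Of 10 cytokines 1 rose and 4 fell, or 1 and 5 when adjusted over the list alone (camera adjusted p = 0.0994). MMP2 and MMP19, matrix metalloproteinases, rose 10.2-fold (3.36 ± 0.44) and 8.96-fold (3.16 ± 0.22), while the kallikreins KLK10 and KLK8 were at least 51.3-fold and 14.99-fold lower (-10.15 ± 0.76 and -6.44 ± 0.57). MMP2 was not called with the mean of its probe sets (0.77), nor KLK8 with its probe set in the completely named part of the array (-3.00). Of 19 proteases and inhibitors 4 rose and 6 fell, or 8 and 8 when adjusted over the list alone (camera adjusted p = 0.857).

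Lists for general cell state shifted little by camera. TYMS, thymidylate synthase, was the only one of 20 cell cycle genes called, 1.90-fold higher (log2 change 0.93 ± 0.21, adjusted p = 0.0335), and none passed when adjusted over the list alone. Its call was lost without any single array (0.88 to 0.98) and with arrays centred on their median, and the list had a camera adjusted p = 0.611. CDKN2C, a cyclin-dependent kinase inhibitor, rose 6.62-fold (2.73 ± 0.27) as the only called gene of 6 cell cycle inhibitors and p53 targets, also when adjusted over the list alone (camera adjusted p = 0.593). IFI44L was at least 10.01-fold higher (7.94 ± 0.85), yet OAS1 and HERC6 were at least 1.10-fold and 3.65-fold lower (-3.40 ± 0.41 and -2.01 ± 0.39), so that of 17 interferon response genes 1 rose and 4 fell, the same when adjusted over the list alone (camera adjusted p = 0.611). The HERC6 call was lost without CD24hi a (-1.65) or MSP1 b (-1.91) or with the mean of its probe sets (-0.47), and another HERC6 probe set gave 0.59. Of 15 hypoxia and glycolysis genes 2 fell, the same when adjusted over the list alone: NDRG1 14.2-fold (-3.82 ± 0.34) and CA9 at least 4.58-fold (-2.92 ± 0.39), with a camera adjusted p = 0.305. Of 14 actin and migration genes RHOB rose 2.89-fold (1.53 ± 0.30) and LIMA1 fell 2.66-fold (-1.41 ± 0.30), or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.858). The RHOB call was lost in 4 of 8 fits that left out an array, those without MSP1 a, MSP1 b, MSP3 a or CD24hi b (lowest 1.28), and with the mean of its probe sets (1.26), and the LIMA1 call in 6, all but those without CD24hi b or MSP3 a (-1.74 to -1.08).

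Cholesterol and lipid synthesis had 0 of 17 members called in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.611), with SCD at 6652 and 5971. Housekeeping genes had 0 of 12 called by both adjustments (camera adjusted p = 0.771), with ACTB at 11720 and 12670. Leukocyte markers had 0 of 6 called by both adjustments (camera adjusted p = 0.857), with CD79A at 60.3 and 72.1, and endothelial markers had 1 of 8 called and 0 when adjusted over the list alone (camera adjusted p = 0.650). That gene, KDR, lay at 3.63 and 11.6 signal units, both within the dim range, and its call was lost in 7 of 8 fits that left out an array, all but MSP2 b (1.47 to 1.88). The sign of the median, mean and test differed in 4 lists that were not called: Wnt receptors (median 0.29, mean 0.09, test down), TGF-beta ligands and receptors (median -0.11, mean 0.29, test up), interferon response (median 0.06, mean -0.02, test down) and actin and migration (median -0.00, mean 0.08, test up).

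**Figure D3:**
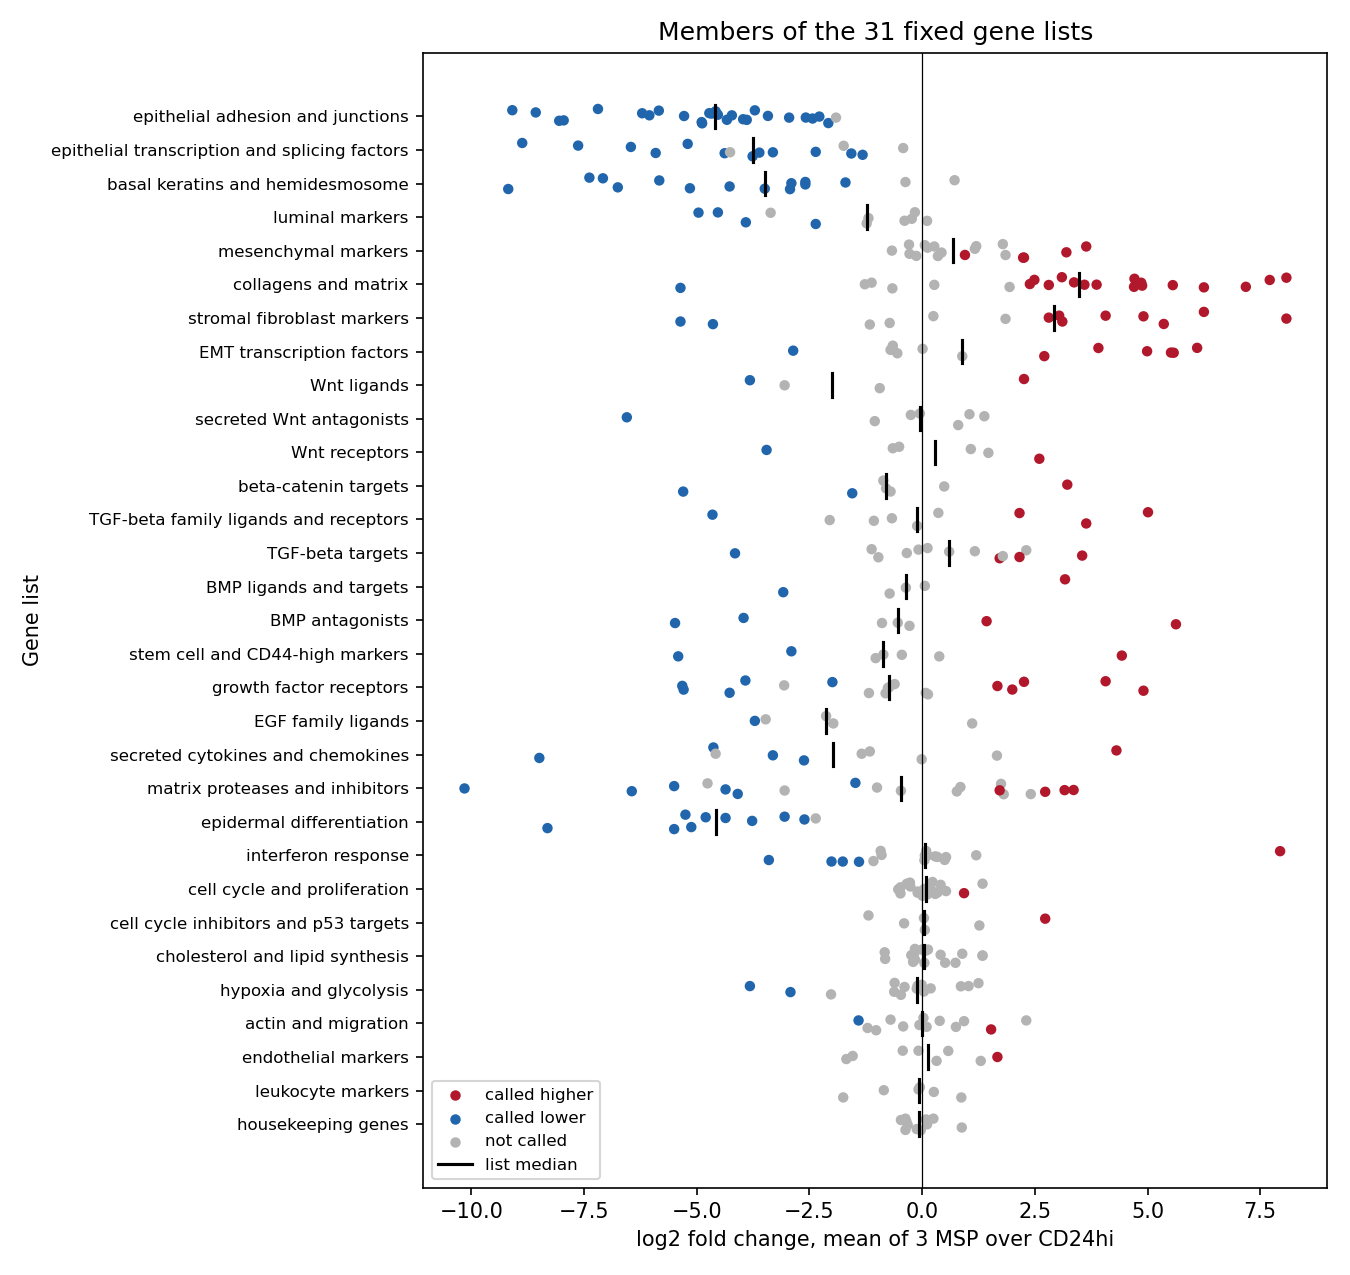
Log2 fold change of the MSP mean over CD24hi for each measured member of the 31 fixed gene lists, with red and blue points for members called higher or lower, grey points for the rest, and a black bar at the list median. The medians of the epithelial adhesion and the matrix lists are -4.59 and 3.49, and that of the housekeeping list is -0.07.

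Set against CD24hi alone, MSP1 had 429 genes higher and 584 lower out of 8926 tested. Genes with wide rises included COL3A1, at least 226-fold (log2 change 7.84 ± 0.43), FBLN5, 210.4-fold (7.72 ± 0.26), ITGBL1, at least 66.1-fold (7.80 ± 0.54), RTN1, at least 25.8-fold (10.16 ± 0.52), and PTGFR, at least 15.5-fold (7.94 ± 0.89). Those with wide falls included CDH3, at least 72.6-fold (-10.60 ± 0.90), KLK10, at least 51.3-fold (-10.26 ± 0.93), COL17A1, at least 36.2-fold (-9.75 ± 0.47), IL1A, at least 27.5-fold (-9.72 ± 0.57), and GJB6, at least 18.4-fold (-10.85 ± 1.09). A log2 change that rests on a dim level gives no order among these genes. With dim levels raised to 32, 345 of the rises and 456 of the falls were at least 2-fold, and 119 of the 1013 calls were dim on both sides. The count fell to 399 without MSP1 a, 393 without MSP1 b, 482 in a fit of these 4 arrays alone, and 209 over the completely named part of the array.

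In MSP2, 418 genes were higher and 529 lower than in CD24hi. Genes with wide rises included COL3A1, at least 300.1-fold (log2 change 8.25 ± 0.43), SDC2, at least 60.2-fold (9.32 ± 1.58), PTGFR, at least 21.2-fold (8.40 ± 0.89), PDGFRL, at least 18.8-fold (7.96 ± 0.54), and IFI44L, at least 14.3-fold (8.45 ± 1.04). Those with wide falls included CDH1, at least 136-fold (-9.67 ± 1.06), KLK10, at least 51.3-fold (-10.13 ± 0.93), ESRP1, at least 37.3-fold (-10.38 ± 0.64), GJB6, at least 18.4-fold (-10.43 ± 1.09), and RAB25, at least 18.3-fold (-9.01 ± 0.89). All of these had a dim level on their lower side. The count of 947 fell to 396 without MSP2 a, 390 without MSP2 b, 377 in a fit of these 4 arrays alone, and 197 over the completely named part.

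MSP3 had 461 genes higher and 537 lower than CD24hi. Rises here included COL3A1, at least 277-fold (log2 change 8.14 ± 0.43), PTGFR, at least 23.9-fold (8.57 ± 0.89), SDC2, at least 23.6-fold (7.97 ± 1.58), IFI44L, at least 11.96-fold (8.20 ± 1.04), and RTN1, at least 10.1-fold (8.81 ± 0.52). Falls included KLK10, at least 51.3-fold (-10.07 ± 0.93), COL17A1, at least 36.2-fold (-9.04 ± 0.47), IL1A, at least 27.5-fold (-8.90 ± 0.57), FAM83B, at least 21.6-fold (-9.32 ± 0.71), and GJB6, at least 18.4-fold (-10.25 ± 1.09). All of these too had a dim level on their lower side. The count of 998 fell to 397 without MSP3 a, 456 without MSP3 b, 650 without either MSP1 array, 390 in a fit of these 4 arrays alone, and 207 over the completely named part.

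Many changes were called in all 3 subpopulations. All 9 gene lists called in the mean comparison were also called by camera against each subpopulation alone, and 0 lists were called with an estimated correlation, where the lowest adjusted p was 0.0887 in MSP1, 0.1003 in MSP2 and 0.0928 in MSP3. In all, 321 genes were higher and 402 lower in every comparison with CD24hi, CDH1, EPCAM, ZEB1 and COL3A1 among them. The means were 0.05 and 0.15 in 20 simulations of unchanged groups with the same controls, and independent lists give 1.04 and 2.08. The simulated groups held no change, so almost no gene could be called there. Those means therefore do not show how far real changes are shared. Neither expectation holds the choice of names: 1078 of the probe sets were named because the authors had called them in all 3 comparisons, and these gave 524 of the 723 shared calls, while the other 7848 gave 199, 93 higher and 106 lower. A fit of the completely named part alone gave 144. Leaving out an MSP array brought the 723 shared calls down to between 326 and 377.

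Fold changes of the comparisons correlated across the 8926 genes, which are not independent replicates, with Pearson coefficients of 0.864 for MSP1 and MSP2, 0.881 for MSP1 and MSP3 and 0.870 for MSP2 and MSP3, against 0.572, 0.571 and 0.567 in simulated unchanged groups. The covariances were 2.19, 2.25 and 2.14, against 0.442, 0.444 and 0.441 in the simulation. No gene was called in opposite directions by any pair. Splitting the 2 CD24hi arrays would leave 1 array for each comparison, so they were not split. The simulated values already hold the spread between these 2 shared arrays, and the excess lies beyond it. A shift common to both CD24hi arrays is not in the simulation, so part of the excess may still come from the shared controls. The choice of names is not in the simulation either. Of the probe sets used for the 8926 genes, 1078 were named because the authors had called them in every comparison with CD24hi. Part of the excess may come from this choice, so these coefficients and covariances need not hold for the rest of the array.

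Between the subpopulations themselves limma called 0 genes in each of the 3 pairs, by all 8 arrays. An unadjusted p under 0.05 was met by 430 genes for MSP2 against MSP1, 349 for MSP3 against MSP1 and 384 for MSP3 against MSP2, where chance gives 446. The a minus b difference that the MSP arrays shared stayed in the error of this fit, so these counts do not show that the subpopulations were alike. CD24 itself read 22.3 in MSP1 and 106 in MSP2 (log2 change 2.25 ± 0.49, adjusted p = 0.400). UCHL1, a ubiquitin hydrolase, picked after its values were seen as was RNF144A below, read 6.57 in MSP1 and 281 in MSP2 (5.42 ± 0.59, adjusted p = 0.159). Epithelial adhesion genes lay higher in MSP2 and MSP3 than in MSP1 by a median of 0.42 and 0.43 on the log2 scale, with 0 members called (camera adjusted p = 0.00402 and 8.50e-05, adjusted p = 0.935 and 0.987 with an estimated correlation). Of its 28 members 14 and 15 were dim in both groups compared, and the medians of the others were 0.69 and 0.38. Basal keratin genes lay higher in MSP3 than in MSP1 by a median of 0.36 (camera adjusted p = 0.00868, adjusted p = 0.987 with an estimated correlation), and stem cell markers lower in MSP2 than in MSP1 by a median log2 change of -0.62 (camera adjusted p = 0.0474, adjusted p = 0.935 with an estimated correlation). Of 15 basal genes 2 were dim in both groups compared, and the median of the others was 0.36. Among 7 stem cell markers 2 were dim in both, and the median of the others was -0.46. With fry, another list test, 0 lists were called in either of these pairs.

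Other settings of limma called few genes between subpopulations. For MSP2 against MSP1, a trended and robust variance called 2 genes, RNF144A and UCHL1, and an offset of 16 called 1, UCHL1. RNF144A read 0.814 in MSP1 and 51.5 in MSP2. Both genes were dim in MSP1, so the size of their log2 changes rests on a dim level. A floor of 32 called 4, 3 and 5 genes in the 3 pairs, among them FABP4, PLCXD3 and ABCB6, each dim on its lower side. The floor sets dim levels to 32 and so removes their spread. FABP4 read 12.7 in MSP1, 5.60 in MSP2 and 74.4 in MSP3. Its log2 change for MSP3 over each other subpopulation was thus at least 1.22, with an SE of 0.01 after the floor. In simulated data for MSP3 against MSP2, the fit called 12% of genes changed 4-fold and 68% of those changed 16-fold. The simulated spread was that of the fit of all 8 arrays, so these shares need not hold for the MSP arrays.

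The authors' deposited table gives a log2 fold change and a p-value for each subpopulation against CD24hi. In the authors' deposited table CDH1 changed by -8.97 in MSP1, -8.37 in MSP2 and -8.07 in MSP3, and COL3A1 by 7.65, 8.09 and 7.93. Across the 16382 listed probe sets its fold changes correlated with those computed here at 0.820 for MSP1, 0.812 for MSP2 and 0.817 for MSP3. Over the completely named part alone the coefficients were 0.689, 0.682 and 0.690. Among the 2466, 2384 and 2458 probe sets with a deposited p-value under 0.05 the coefficients were 0.954, 0.954 and 0.954. The direction was the same for 99.96%, 100% and 99.88% of them. Only 740, 656 and 672 of them were also called here in the fit of all probe sets. The slope of the deposited on the present fold changes was 0.53 over all listed probe sets. For single bright genes the values lay close or went either way: in the authors' deposited table CCN2 changed by 3.59 in MSP1, against 3.58 here, and GREM1 by 6.19, against 5.73 here. VIM, not called here with changes of 0.29, 0.50 and 0.49, changed by 0.74, 0.75 and 0.76 in the authors' deposited table, with p-values of 0.0451, 0.0462 and 0.0407.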

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

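All tests in this part were chosen after the results they bear on had been seen, and no biological explanation was tested, since the labels give no difference between arrays a and b.

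The CD24hi arrays differed over 2-fold at 23.5% of bright probe sets, further apart than any MSP pair. Mesenchymal cells left in a sort would bring all their abundant transcripts, but the 10 most abundant genes that were higher in all 3 MSP groups had a median of 4.93% of their MSP level in the higher CD24hi array, and COL3A1 stood at 0.305% and 0.449%. The a minus b difference also did not follow the mesenchymal change, with a correlation of -0.0318 across 13551 bright probe sets. Matrix genes lay higher on CD24hi a by a median of 0.96, and epithelial adhesion genes by 0.98. These lists change in opposite directions in the MSP groups and so offset each other in that correlation. A value near 0 therefore cannot by itself exclude a part for mesenchymal transcripts. A difference in RNA input or labelling may contribute and stays open: the Bacillus control transcripts, which came to notice as a signal in control probe sets that no comparison uses, were 10.2 times higher on CD24hi a than on b, against 1.37 to 1.44 times in the MSP groups.

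The a minus b difference was shared by the 3 MSP groups, with correlations of 0.723 to 0.846 across bright probe sets, and opposed in CD24hi. A single shift per letter on all 8 arrays, as the main difference, would make every pair correlate above 0. Instead, CD24hi and MSP differences correlated at -0.462 to -0.347. A smaller shift of this kind stays open. On the third principal component (9.22% of variance) CD24hi lay at -22.4 on a and 17.3 on b. The MSP arrays lay there at -26.0 to -0.294 on a and 13.9 to 18.4 on b. Shared handling of the MSP arrays of each letter may account for their part and stays open, since the control ratios of the 3 MSP groups lay within 1.05 times of each other.

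No gene was called between MSP groups in the fit of all 8 arrays. Taking away the wide spread of the CD24hi arrays was not enough to give calls, as a fit with only the 6 MSP arrays also called 0 genes. That fit has fewer arrays for its error, so it cannot exclude a part for this spread. Its limma fit had 543, 397 and 468 genes at an unadjusted p under 0.05, against 430, 349 and 384 with all 8 arrays. A contribution of the spread stays open. Too little power for small changes cannot be told apart from their absence, as 0% of simulated 2-fold changes were called for MSP3 against MSP2. The simulated spread was that of the fit of all 8 arrays, so this share need not hold for the MSP arrays. Too little power for large changes stays open too: the simulation called 68% of 16-fold changes, but ANPEP, at 32.8-fold between MSP2 and MSP3 (adjusted p = 0.385), was not called.

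Of the 40587 probe sets with no gene name here, 458 were called between the MSP mean and CD24hi, 263 higher and 195 lower. Over the whole array 1731 of 54613 were called, so the unnamed probe sets hold a small part of the calls. This is a signal in probe sets that the gene comparisons do not use.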

How the results depend on the processing

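Counts of genes called against CD24hi depended most on the threshold, the arrays kept and the gene names, and the causes of these moves were not tested. At an adjusted p under 0.01 the counts were 372 for MSP1, 356 for MSP2, 359 for MSP3, 688 for the MSP mean and 264 in all 3, against 1013, 947, 998, 1428 and 723. The completely named part of the array gave 209, 197, 207, 345 and 144. It holds 8121 of the 8926 genes and leaves out the probe sets named only because the authors had called them. Fits of only the groups compared gave 482, 377 and 390. Leaving out each array in turn gave 393 to 818 for MSP1, 390 to 714 for MSP2, 397 to 760 for MSP3, 1001 to 1133 for the mean, 326 to 564 in all 3, and 0 in each MSP pair. The subpopulation as a random block called 2333 for the mean, with a negative consensus correlation of -0.339, and an offset of 16 called 1228 in all 3. Quantile normalization (1029, 972, 999, 1447 and 744) and median centring (1003, 910, 951, 1329 and 708) moved little. Between MSP2 and MSP1, trend and robust called 2 genes, the offset of 16 called 1, and the floor of 32 called 4, with 3 for MSP3 against MSP1 and 5 for MSP3 against MSP2. Correlations over genes above the median level were 0.955, 0.970 and 0.965, against 0.864, 0.881 and 0.870. Of the gene lists, camera called 9, camera with an estimated correlation 0, and fry 17. Fry alone called Wnt ligands, secreted Wnt antagonists, beta-catenin targets, TGF-beta targets, EGF family ligands, cytokines, hypoxia and glycolysis, and endothelial markers. With only genes above the median level, 1 list lost its camera call. An offset of 16 added 2 lists and the mean of a gene's probe sets added 1. The completely named part lost 1 and added 1. The offset, the floor, the counts over all probe sets, the completely named part and the MSP arrays alone were chosen after the data were seen. With other probe sets in the completely named part, CD24 changed by 0.06 and HERC6 by 0.59, opposite in sign to -6.35 and -2.01.

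The labels give arrays of the same letter only that letter in common. The a minus b differences correlated at 0.723 to 0.846 among the MSP groups and at -0.462 to -0.347 between these and CD24hi. These correlations hint at pairing for the MSP arrays only. The third principal component (9.22% of variance), however, parted a from b in the same direction in all 4 groups. With the letter as a replicate block the counts were 906, 853, 854, 1325 and 655, with 836, 784, 797, 1255 and 603 of these genes shared with the fit without it, and 0 in each MSP pair; CDH2, KDR, NOG and WNT5B were not called with it. A replicate block on only the 6 MSP arrays, chosen after the data were seen, also called 0 genes in each pair, with 804, 603 and 681 genes at an unadjusted p under 0.05 where chance gives 446.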

Other observations

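The gene groups that separated the arrays a and b were examined after the values were seen, as medians set against 10000 random lists matched on level; they describe these arrays only. In the MSP groups, cell cycle genes lay lower on the a arrays by a median log2 difference of -0.50 and cholesterol synthesis genes by -0.47, both below every random list. Interferon response genes lay higher on the a arrays by 0.71, above every random list, stromal fibroblast markers by 0.62 (percentile 99.99), and cell cycle inhibitors and p53 targets by 0.73 (percentile 99.97). Between the CD24hi arrays the order of cell cycle inhibitors and p53 targets was turned, with a median of -1.07 (percentile 0.24), while cholesterol genes lay higher on array a by 0.67 (percentile 99.81).

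Epithelial adhesion genes and matrix genes both lay higher on CD24hi a, by medians of 0.98 and 0.96, above every random list, as did proteases and inhibitors by 1.16. Among single genes CXCL1, a chemokine, read 1194 on CD24hi a and 76.2 on b, and IGFBP3 read 387 and 65.8. TXNIP, a thioredoxin inhibitor, read 107 and 770, PDCD4 97.6 and 638, and GLUL, glutamine synthetase, 337 and 2863. These genes were chosen for their differences and have no replicate check.

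Some genes lay far apart between subpopulations without passing the test. ANPEP, a membrane aminopeptidase, read 66.0 in MSP1, 1149 in MSP2 and 34.99 in MSP3 (MSP3 over MSP2 log2 change -5.04 ± 0.82, adjusted p = 0.385). HOXB7 read 54.3, 38.0 and 162 (MSP3 over MSP2 2.09 ± 0.30, adjusted p = 0.384), and KRT5, a basal keratin, 80.6, 391 and 327 (MSP3 over MSP1 2.02 ± 0.45, adjusted p = 0.685). GULP1 read 124, 681 and 144 (MSP3 over MSP2 -2.24 ± 0.40, adjusted p = 0.471). All were among the smallest unadjusted p-values of genes whose mean in either group compared passed the level set for bright probe sets.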
